A study of Mus musculus with 9 samples.

How the data were processed

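RNA from mouse skin was measured by sequencing in 9 libraries, 3 each of C57BL/6, BALB/c and mice labelled as IL-6-deficient. The labels list 3 C57BL/6, 3 BALB/c and 6 IL-6-deficient mice in the protocol and do not tie each library to 1 mouse. The mice arrived at 4 to 5 weeks of age, were acclimated for 2 weeks, were shaved on day 0, received no treatment for 7 days, and gave skin on day 8. Sex is not given in the labels used here, so sex-linked genes were read.

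The authors mapped the reads to a mouse genome (GRCm38, per the submitters' processing notes) and counted them per gene. The deposited counts are raw, per the file headers. The aligner, its version and its settings are not given in the sources used here. The deposited RPKM values follow from total exon reads, exon length and library size in 100% of genes above 50 reads in each table. RPKM was not used further. Each table holds 49585 genes, of which 17474 have no annotated transcript and no exon reads. The file of C57BL/6 replicate 1 holds 3 tables, the later 2 of which are identical in each cell to those of replicates 2 and 3, and the first was used. The deposited Expression value column, also in counts, equals total exon reads in all genes of the tables labelled IL-6 KO, whereas in the others it equals unique exon reads plus multi-mapped exon-exon reads. Total exon reads, which have 1 meaning in each table, were therefore the counts analysed. The tables labelled IL-6 KO also lack a column of gene biotypes that the others hold.

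Counts were analysed in R 4.3.3 with edgeR 4.0.16, all 9 libraries in 1 model with a coefficient per group and 6 residual degrees of freedom. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 14415, and libraries were scaled by TMM (factors from 0.887 to 1.10). The common dispersion was 0.0524. Pairwise differences and the joint difference among groups were tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. A gene is apart in a group when it was called in the same direction against both others. Gene lists, 35 in all, were written from general knowledge, and the 33 with at least 5 tested members were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over all 99 tests. Camera with an estimated correlation and fry were run beside it. Within each list, p-values were also adjusted over its members alone. The lists, the comparisons and their tests, the alternatives listed as planned and the rule for named genes were fixed before the data were examined. Further alternatives and tests of explanations were added after seeing the data.

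The named genes are Il6, Tyr, Nnt, H2-Ea-ps and sex-linked genes as a check of the labels. To these the rule adds the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap and whose mean reaches 5 CPM in the higher group, leaving out predicted genes, clone names, pseudogenes, small RNAs and antigen receptor segments. It also adds up to 4 members, by p-value, of each list that passed its test, had at least 3 called members, or concerns IL-6 or a T helper type, and 5 genes per direction for each group apart. For a gene with 0 reads in a group, the fold is a bound against 3 reads over that group. For 1 to 3 reads, the ratio is given with its 95% counting interval.

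From 17339 to 18050 genes had at least 1 read in a library. Replicates spread more than counting error allows, with chi-square per degree of freedom from 4.39 to 48.5, so counting intervals understate the error between libraries. The test was tried on simulated counts with the depth and dispersion of these libraries: 100 genes changed 2-fold and 100 changed 4-fold among 14415. The same simulation gave 3.25% false calls for BALB/c against C57BL/6 and 7.52% for the libraries labelled IL-6 KO against C57BL/6, and 0 of 4 unchanged random lists were called beside a raised one. The overlap between comparisons that share C57BL/6 was set against 20 simulations of unchanged groups. Genes within 20 Mb of Il6 were compared with all others by Fisher's exact test.

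Near-identical copies were found by aligning reference transcripts (GENCODE vM21) to each other with blastn 2.17.0 and seqkit 2.13.0, with at least 95% identity over at least 200 bases and 40% of the shorter transcript. Reads of a gene and its copies were added, and 0.1 CPM was added before the log ratio. Alternatives planned were RLE normalization, no filter, a robust variance model, a block for the replicate number, a minimum log2 fold change of 1, models of only the groups compared, DESeq2 1.42.0, the other list tests, other windows around Il6, and leaving out each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Krt85, a hair keratin, is absent from the tables.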

Results

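Skin RNA of 3 kinds of mice was compared. C57BL/6 and BALB/c are inbred strains whose T helper responses are often described as leaning to Th1 and to Th2. The remaining mice were labelled as deficient in interleukin-6 (IL-6), a cytokine that signals through Il6ra and Il6st to STAT3. According to the labels, the animals were 6 weeks old at the start, were shaved on day 0, and gave skin on day 8. Each group had 3 libraries, and the labels do not tie a library to 1 mouse, so p-values measure the spread between these libraries, which may in part be technical. Total exon reads were 6882193, 6530963 and 6083876 in the C57BL/6 libraries, 6242332, 6115739 and 6152688 in BALB/c, and 3843953, 4476346 and 4414818 in the libraries labelled IL-6 KO. Levels are counts scaled to library size (CPM), mean ± SD over the 3 libraries of a group. Fold changes are log2 values ± SE, single-gene adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and "higher", "lower" and "called" refer to an adjusted p under 0.05. Counting intervals and floors cover counting error only.

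The gene targeted in the knockout was examined first. Il6 (chromosome 5, 30013114 to 30019981, GRCm38) had 2, 1 and 0 exon reads in the C57BL/6 libraries, 0, 2 and 0 in BALB/c, and 6, 24 and 1 in the libraries labelled IL-6 KO. It was too rare to be tested among the filtered genes. Without the filter its log2 fold change was 3.62 ± 1.14 against C57BL/6 (adjusted p = 0.0381) and 4.09 ± 1.21 against BALB/c (adjusted p = 0.0272), so the reads run against the label. Reads were counted over the whole gene, and the labels do not say which part was deleted, so reads of a truncated transcript would be counted too. For this reason these libraries are called "the libraries labelled IL-6 KO" throughout, "IL-6 KO replicate" names 1 of them by its label, and every direction given for them rests on that label.

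Of the other genes of the label check, H2-Ea-ps and Nnt differed between the strains. H2-Ea-ps, the class II alpha chain gene that is silent in mice of the H2b haplotype such as C57BL/6 (chromosome 17, 34342933 to 34344643), had 325, 469 and 548 reads in BALB/c and 0 in each other library. Its level of 72.9 ± 19.1 CPM in BALB/c was at least 451-fold higher than in C57BL/6 and at least 325-fold higher than in the libraries labelled IL-6 KO, with 3 reads over the group as the floor. Nnt, a mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J (chromosome 13, 119335448 to 119408997), stood at 32.6 ± 3.70 CPM in C57BL/6, 88.6 ± 17.9 in BALB/c and 12.0 ± 4.32 in the libraries labelled IL-6 KO. It was higher in BALB/c than in C57BL/6 (1.44 ± 0.231, adjusted p = 0.0108). The Nnt call ended without C57BL/6 replicate 1 or 3 or BALB/c replicate 2 or 3 (adjusted p from 0.0546 to 0.0573, and from 3.04e-06 to 0.0573 over all alternatives). Nnt was lower in the libraries labelled IL-6 KO than in C57BL/6 (−1.44 ± 0.252, adjusted p = 0.00267). Tyr, the rate-limiting enzyme of melanin synthesis (chromosome 7, 87424771 to 87493512), was at 58.4, 4.07 and 71.8 CPM in the libraries labelled IL-6 KO and at 0.413 ± 0.295 and 0.267 ± 0.244 in C57BL/6 and BALB/c. Of the list of strain markers, 9 were measured. In BALB/c 3 were higher and 1 lower than in C57BL/6 (3 and 3 adjusted over the list alone), in the libraries labelled IL-6 KO 2 were higher and 2 lower than in C57BL/6, and 3 were higher and 3 lower than in BALB/c, on either adjustment. Camera, the set test used for every list, did not call it in any comparison (adjusted p = 0.495 for BALB/c and 0.801 for the libraries labelled IL-6 KO against C57BL/6, and 0.534 between those groups). Its median and mean differed in sign in both comparisons of the libraries labelled IL-6 KO.

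Y-linked transcripts were present in each library. Eif2s3y stood at 59.5 ± 3.48, 62.0 ± 8.02 and 61.1 ± 12.0 CPM and Kdm5d at 27.1 ± 5.14, 30.4 ± 4.11 and 27.7 ± 1.87 CPM in C57BL/6, BALB/c and the libraries labelled IL-6 KO. Uty was higher than in C57BL/6 in BALB/c (0.99, adjusted p = 0.0291) and in the libraries labelled IL-6 KO (0.71, adjusted p = 0.022). So was Ddx3y (1.14, adjusted p = 0.0299, and 0.88, adjusted p = 0.0159). In BALB/c, leaving out C57BL/6 replicate 2 or any BALB/c library ended both calls. C57BL/6 replicate 1 or 3 or IL-6 KO replicate 3 also ended that of Uty, as did the replicate block (adjusted p = 0.0548, and over all alternatives from 0.00134 to 0.0938 for Uty and from 4.61e-04 to 0.107 for Ddx3y). In the libraries labelled IL-6 KO, the Uty call ended without C57BL/6 replicate 1 or 3 or IL-6 KO replicate 1 or with only the groups compared (adjusted p up to 0.0806, and from 0.011 to 0.0806 over all alternatives), and that of Ddx3y without IL-6 KO replicate 1 (adjusted p = 0.0539, and from 0.00351 to 0.0539). Of the 4 measured members of the sex-linked list, too few for a set test, 2 were called in each of these comparisons and 0 between BALB/c and the libraries labelled IL-6 KO. Xist, the transcript of the inactive X chromosome, had 130 reads in BALB/c replicate 2 and 5 or fewer in each other library. The origin of the RNA in that library is therefore in doubt, and its values are part of each BALB/c mean. Its Y-linked levels were like those of BALB/c replicates 1 and 3 (Eif2s3y at 71.0 CPM against 59.4 and 55.6). It lay close to BALB/c replicate 3, with a chi-square per degree of freedom of 4.39. Without it 179 genes, against 491, were called between the strains. Without BALB/c replicate 3 the count was 167, so the drop is not particular to this library.

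The libraries labelled IL-6 KO lay far from both strains, and the strains lay close together. The first principal component of log2 CPM held 68.0% of the variance and placed the libraries labelled IL-6 KO at scores of 119, 64.8 and 111, with C57BL/6 at −26.6, −33.5 and −58.9 and BALB/c at −56.0, −62.5 and −57.5. The second component, with 13.3% of the variance, separated BALB/c from C57BL/6. Across genes, which are not independent replicates, the mean correlation was 0.965 within C57BL/6, 0.970 within BALB/c and 0.947 within the libraries labelled IL-6 KO. It was 0.930 between the strains, and 0.806 and 0.769 between the libraries labelled IL-6 KO and C57BL/6 or BALB/c.

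**Figure D1:**
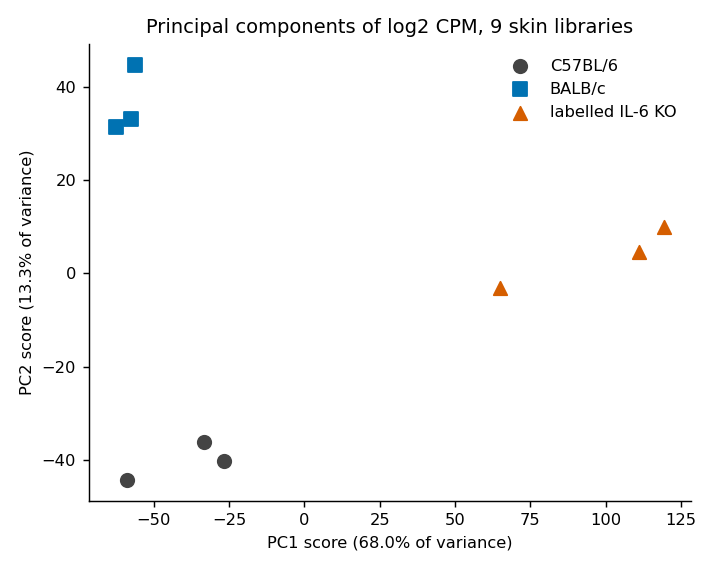
Scores of the 9 libraries on the first and second principal components of log2 CPM (axes in score units, with the percent of variance), with 1 symbol per library and 1 colour per group. The libraries labelled IL-6 KO sit at 64.8 to 119 on the first component, and the other libraries sit at −26.6 or below.

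BALB/c skin was compared with C57BL/6 skin because the strains model different T helper balance. BALB/c skin gave reads of several immune genes that C57BL/6 skin all but lacked. Gbp2b, an interferon-inducible guanylate-binding protein (chromosome 3, 142594847 to 142619179), reached 18.0 ± 4.46 CPM in BALB/c (SD, n = 3) against 3 reads in all C57BL/6 libraries, a ratio of 112 (95% counting interval 37.9 to 545). H2-Q1, a nonclassical class I gene of the major histocompatibility complex (chromosome 17, 35320405 to 35325099), reached 30.5 ± 2.39 CPM with a ratio of 284 (78.3 to 2351). Whether reads of other BALB/c class I genes were assigned to it was not tested. Interferon-induced Ifi44l reached 6.08 ± 0.856 CPM with a ratio of 113 (19.8 to 4496). In the other direction, Skint9, Skint3 and Skint4, of a family of immunoglobulin-like membrane proteins made in epidermis and thymus, stood at 47.3 ± 13.0, 32.4 ± 12.2 and 22.6 ± 8.53 CPM in C57BL/6. Skint9 (chromosome 4, 112385969 to 112433985) and Skint3 (chromosome 4, 112232245 to 112300468) had 0 reads in BALB/c, which made them at least 297-fold and 205-fold lower there, and the ratio for Skint4 was 143 (48.6 to 696).

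The calls of these genes had adjusted p-values of 3.26e-04 for Gbp2b, 9.11e-06 for H2-Q1, 0.00165 for Ifi44l, 0.00796 for Skint9, 0.0081 for Skint3 and 0.00372 for Skint4. Of 14415 genes tested, 491 were called (3.41%), with 235 higher and 256 lower in BALB/c, and 332 of them differed at least 2-fold. The 3 BALB/c values of all 491 lay above or below the 3 C57BL/6 values. Chance gives this for 10% of genes not chosen by a test, and these were chosen by a test of the same values, so the count is no separate evidence. With library size alone as the scaling, 58.8% of the called genes were higher in BALB/c, against 47.9% here. DESeq2 called 1023 genes. The count fell to 243, 285 and 221 without C57BL/6 replicate 1, 2 or 3, to 246, 179 and 167 without BALB/c replicate 1, 2 or 3, and to 309 without IL-6 KO replicate 3. It was 977 without IL-6 KO replicate 2, and all 9 libraries shared 1 estimate of the spread. In simulated counts of this comparison, 33% of 100 genes changed 2-fold and 86% of 100 changed 4-fold were recovered, with no other gene changed.

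Several of the largest strain differences lay in genes with near-identical copies, whose reads can be assigned to either copy. C1rb, of the complement C1r pair, had 16.9 ± 1.69 CPM in BALB/c and 0 reads in C57BL/6, at least 105-fold. The summed reads of C1rb and its 2 copies, C1ra among them, differed by 0.14 on the log2 scale. Eno1b, a copy of the enolase gene Eno1, had 143 ± 51.5 CPM against 0.356 ± 0.388 (8.50 ± 0.525, adjusted p = 3.47e-05). The sum with Eno1 differed by 0.19. For Serpina1b, an alpha-1 antitrypsin gene that was at least 73.2-fold higher in BALB/c (11.7 ± 8.51 CPM), the sum with its copies kept a difference of 4.43. Among the genes lower in BALB/c, Rpl29, a protein of the large ribosomal subunit (chromosome 9, 106429454 to 106431568), fell from 364 ± 30.0 to 2.00 ± 0.0621 CPM (−7.49 ± 0.226, adjusted p = 5.54e-07). A change of −7.26 was left when the reads of its 2 copies were added. Reads that were not mapped, or that went to other sequences, are not in this sum, and this was not tested. The same limit applies to the genes with 0 reads in BALB/c. Among major urinary protein genes, a cluster of near-identical carriers of pheromones, calls went both ways. Mup11 fell to 0.333 ± 0.576 CPM in BALB/c (−9.18 ± 1.14, adjusted p = 0.00297), and the sum with its copies differed by −2.87. Mup17, chosen after its values were seen, stood at 1.69 ± 1.75 CPM in C57BL/6 and 24.1 ± 14.2 in BALB/c and was called higher. The interferon-induced GTPase Gvin1 had 0 reads in BALB/c, at least 115-fold lower, while its sum with a copy differed by −0.52. Its call was lost with the Expression value column of the tables (−5.23, adjusted p = 0.151, from 1.77e-10 to 0.151 over all alternatives). Trim12a, of the TRIM5 family, had 17.3 ± 2.16 CPM in C57BL/6 and 0 reads in BALB/c, at least 106-fold lower (adjusted p = 6.5e-04). A further 17 higher and 3 lower genes had names that the rule for named genes passes over.

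The vessel and matrix lists had medians below 0 in BALB/c skin, with few members called. The endothelial list had 3 of 25 measured members lower (7 adjusted over the list alone), a median of −0.71 and an adjusted p of 6.53e-08 in camera, with adjusted p = 0.638 with an estimated correlation. Vwf, the von Willebrand factor of endothelium and platelets (chromosome 6, 125546774 to 125686679), fell from 67.1 ± 16.1 CPM in C57BL/6 (−1.54 ± 0.246, adjusted p = 0.0105, but 0.0573 without BALB/c replicate 3, from 2.50e-06 to 0.0573 over all alternatives). The matrix and fibroblast list had 4 of 39 lower (9 adjusted over the list alone), a median of −0.76 and adjusted p = 2.62e-06, with adjusted p = 0.918 with an estimated correlation. Fmod, the collagen-binding proteoglycan fibromodulin (chromosome 1, 134037254 to 134048277), fell from 32.9 ± 1.42 to 6.51 ± 0.842 CPM (−2.33 ± 0.237, adjusted p = 9.03e-04). Skeletal muscle transcripts were 10.6 ± 2.40% of exon reads in C57BL/6 and 7.25 ± 2.53% in BALB/c. The muscle list had 1 of 30 lower (2 adjusted over the list alone), a median of −0.52 and adjusted p = 7.15e-05 (0.918 with an estimated correlation). That call was lost without BALB/c replicate 1 (adjusted p = 0.122, from 1.15e-07 to 0.122 over all alternatives, median −0.26), the library with the lowest muscle share of both strains, 4.34%. Its median was −0.27 without C57BL/6 replicate 3. Its called member was Actn3, the alpha-actinin of fast fibres (chromosome 19, 4861223 to 4877909), which fell from 2680 ± 536 to 708 ± 186 CPM (−1.92 ± 0.254, adjusted p = 0.0043).

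The epidermal differentiation list had a median above 0 in BALB/c, with few members called. Of 57 measured members, 4 were higher and 0 lower (11 and 1 adjusted over the list alone), with a median of 0.54 (0.36 without C57BL/6 replicate 3) and adjusted p = 2.46e-07, against adjusted p = 0.918 with an estimated correlation. Sprr1b, a precursor of the cornified envelope (chromosome 3, 92436809 to 92438789), rose from 0.515 ± 0.293 to 3.69 ± 0.650 CPM (2.74 ± 0.436, adjusted p = 0.0105). Lce1g, a late cornified envelope gene, rose from 3.41 ± 1.17 to 32.0 ± 4.92 CPM (3.24 ± 0.527, adjusted p = 0.0118). Its call was lost without C57BL/6 replicate 1 or 2 (adjusted p from 0.0507 to 0.0592, and from 1.83e-08 to 0.0592 over all alternatives). The sebaceous gland and lipid list had 2 of 34 members higher and 0 lower (6 and 1 adjusted over the list alone), a median of 0.51 and adjusted p = 2.15e-04 (0.893 with an estimated correlation). This became 0.0698 with a median of 0.27 without BALB/c replicate 1 (from 2.39e-06 to 0.0698 over all alternatives). Elovl3, a fatty acid elongase of sebaceous glands, rose from 10.6 ± 1.57 to 37.3 ± 11.2 CPM (1.81 ± 0.300, adjusted p = 0.0129). That of Elovl3 was lost without C57BL/6 replicate 1 or 3 (adjusted p from 0.0546 to 0.0603, and from 4.25e-06 to 0.0603 over all alternatives).

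The hair follicle lists had medians below 0 in BALB/c, with few or 0 members called. The hair shaft list of keratins and keratin-associated proteins took 0.0133 ± 0.0137% of reads in C57BL/6 and 0.00221 ± 0.000708% in BALB/c. C57BL/6 replicate 3, at 0.00225%, lay within the BALB/c range, and below it for the inner root sheath (0.0458% against at least 0.0491%). By share, both differences rest on replicates 1 and 2. Of its 62 measured members, edgeR called 0, over all genes or adjusted over the list alone (24 had an unadjusted p under 0.05, and DESeq2 called 12), and 34 had 0 reads in a group. Its median was −4.45 as fitted and −2.72 with those members at their bounds, with adjusted p = 1.99e-07 in camera and adjusted p = 0.918 with an estimated correlation. The fitted median was −2.39 without C57BL/6 replicate 1. In the inner root sheath list edgeR called 0 of 37 members (4 lower adjusted over the list alone, 13 at an unadjusted p under 0.05, 6 by DESeq2), with a median of −0.68 (−0.41 with bounds) and adjusted p = 0.00344, against 0.918 with an estimated correlation. It had adjusted p = 0.0734 and a median of −0.42 without C57BL/6 replicate 2 (from 4.18e-07 to 0.0734 over all alternatives). The list of follicle stem cells and the resting follicle had 3 of 20 lower (3 adjusted over the list alone), a median of −0.52 and adjusted p = 0.00185 (0.562 with an estimated correlation). Krt24, a keratin of resting follicle stem cells, was among them (9.42 ± 2.41 and 0.761 ± 0.255 CPM, −3.59 ± 0.613, adjusted p = 0.0142). Krt24 lost its call without C57BL/6 replicate 3 or any BALB/c library (adjusted p from 0.0593 to 0.0769, and from 1.45e-05 to 0.0769 over all alternatives).

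Camera called 3 more lists at its preset correlation, with few or 0 members called. Mitochondrially encoded transcripts made up 6.91 ± 1.79% of exon reads in C57BL/6 and 9.94 ± 2.07% in BALB/c, with 0 of 13 genes called by edgeR on either adjustment (3 at an unadjusted p under 0.05, 1 by DESeq2) and a median of 0.40. Their camera call (adjusted p = 0.00255, and 0.918 with an estimated correlation) was lost without C57BL/6 replicate 2 (adjusted p = 0.0775, from 2.23e-06 to 0.0775 over all alternatives, median 0.24). The median was 0.72 without C57BL/6 replicate 3 and 0.24 without BALB/c replicate 1. Cell cycle genes had 0 of 34 called by edgeR on either adjustment (6 at an unadjusted p under 0.05, 1 by DESeq2), a median of 0.31 and adjusted p = 0.0116, against 0.938 with an estimated correlation. The adjusted p was 0.166 and 0.108 without C57BL/6 replicate 3 or BALB/c replicate 3 (from 6.93e-04 to 0.166 over all alternatives). The median was 0.49 without C57BL/6 replicate 2. Antigen presentation genes had 2 of 32 higher, among them H2-Ea-ps (3 adjusted over the list alone), a median of 0.15 and adjusted p = 0.0226, against 0.938 with an estimated correlation. That call was lost without C57BL/6 replicate 2 (adjusted p = 0.127) or BALB/c replicate 2 or 3 (adjusted p = 0.0504 and 0.107, from 0.00337 to 0.127 over all alternatives). Their median was 0.22 without C57BL/6 replicate 1 and 0.30 without BALB/c replicate 1.

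The T helper lists showed no shift between the strains that camera called. Only 10 of 27 type 1 genes, 17 of 30 type 2 genes and 10 of 28 Th17 genes were measured after the filter. The question stays open for the rest. Of 17 measured type 2 genes, 1 was higher (1 higher and 1 lower adjusted over the list alone) and the list had a median of 0.23 (adjusted p = 0.299). The called member was Ccl24, the eosinophil attractant eotaxin-2 (chromosome 5, 135569937 to 135573049), at 9.88 ± 3.92 CPM in C57BL/6 and 28.5 ± 9.05 in BALB/c (1.53 ± 0.352, adjusted p = 0.0486). Its call was lost without any library except IL-6 KO replicate 2 and BALB/c replicate 1 (adjusted p from 0.0615 to 0.166, and with only the groups compared, the replicate block or a robust variance model 0.0553, 0.107 and 0.0509, and from 0.00363 to 0.166 over all alternatives). Retnla, a type 2 product of macrophages, stood at 128 ± 81.7 and 344 ± 97.4 CPM and was not called (1.42 ± 0.526, adjusted p = 0.183). Of 10 measured type 1 genes edgeR called 0 on either adjustment and DESeq2 0, with 3 at an unadjusted p under 0.05 (median 0.00, mean −0.14, which differ in sign, adjusted p = 0.792 in camera). Il12rb2, a chain of the interleukin-12 receptor, had 11.6 ± 5.88 and 4.84 ± 2.15 CPM (−1.26 ± 0.514, adjusted p = 0.221). Of 10 genes of the Th17 and IL-23 axis edgeR called 0 on either adjustment, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (median 0.11, adjusted p = 0.518). In the IL-6 family and STAT3 list edgeR called 0 of 27 (1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 by DESeq2), with a median of 0.02, a mean of −0.05, which differ in sign, and adjusted p = 0.656.

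Lists of other cells and responses were not called between the strains. Their adjusted p-values in camera were 0.0511 for adipocytes (median 0.69), 0.126 for T cells, 0.191 for nerve, 0.213 for basal keratinocytes, 0.214 for neutrophils, 0.279 for interferon-stimulated genes, 0.356 for xenobiotic response, 0.361 for epidermal stress, 0.362 for mast cells, 0.398 for blood and 0.463 for melanocytes. For macrophages, immediate early genes, glucocorticoid response, circadian clock, regulatory T cells and antimicrobial peptides they were 0.534, 0.609, 0.671, 0.801, 0.855 and 0.896. The median and mean of the antimicrobial list, −0.04 and 0.13, differed in sign. Epidermal stress genes had 2 of 16 higher (5 higher and 2 lower adjusted over the list alone), melanocyte genes 1 of 19 lower (1 higher and 2 lower) and antimicrobial genes 1 of 23 higher and 2 lower (2 and 3). On either adjustment, 2 of 42 interferon-stimulated genes were higher, 2 of 39 xenobiotic response genes higher and 1 lower, 1 of 29 macrophage genes higher and 1 lower, and 1 of 18 nerve genes lower. EdgeR called 0 glucocorticoid response genes over all genes (2 lower adjusted over the list alone, 5 at an unadjusted p under 0.05, 2 by DESeq2) and 0 regulatory T cell genes (1 higher adjusted over the list alone, 4 and 1). It called 0 members of the adipocyte, T cell, basal keratinocyte, neutrophil, mast cell, blood, immediate early and clock lists on either adjustment, with 4, 1, 3, 2, 2, 2, 4 and 3 at an unadjusted p under 0.05 and 1, 0, 0, 1, 0, 0, 2 and 0 called by DESeq2. Single members stood out. Pglyrp4, a peptidoglycan recognition protein, fell from 30.0 ± 16.2 to 1.36 ± 0.211 CPM (−4.45 ± 0.592, adjusted p = 0.0043). Defb14, a beta-defensin, rose from 0.375 ± 0.0701 to 6.04 ± 1.66 CPM (3.93 ± 0.582, adjusted p = 0.00757), and Mertk, a receptor for the uptake of apoptotic cells, fell by 1.19 on the log2 scale (SE 0.178, adjusted p = 0.0081). The B cell list had 4 measured members, too few for a set test, of which edgeR called 0 on either adjustment, with 0 at an unadjusted p under 0.05 and 0 by DESeq2.

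The libraries labelled IL-6 KO were compared with C57BL/6 to ask about IL-6 in shaved skin. These libraries were rich in hair transcripts. Hair shaft genes took 3.46 ± 2.08% of exon reads (SD, n = 3), against 0.0133 ± 0.0137% in C57BL/6, and inner root sheath genes 4.70 ± 2.49% against 0.0843 ± 0.0366%. Tchh, the structural protein trichohyalin of the inner root sheath (chromosome 3, 93442330 to 93449077), rose from 115 ± 152 to 15410 ± 9104 CPM (7.06 ± 1.37, adjusted p = 0.00423). Skeletal muscle transcripts moved the other way, from 10.6 ± 2.40% to 1.74 ± 0.152% of reads. Myh4, the myosin of fast fibres (chromosome 11, 67238029 to 67260446), fell from 18111 ± 5164 to 638 ± 311 CPM (−4.83 ± 0.474, adjusted p = 4.29e-04).

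Of 14415 genes, 5068 were called (35.2%), 2767 higher and 2301 lower in the libraries labelled IL-6 KO, and 2709 differed at least 2-fold. The values of 4910 of the called genes did not overlap between the groups, as they do by chance for 10% of genes not chosen by such a test. Library size alone as the scaling put the median of all genes at 0.15 (log2), against 0.01 here, and 67.8% of its calls were higher against 54.6% here. Without IL-6 KO replicate 3 the count was 3238. In simulated counts of this comparison, 35% of 100 genes changed 2-fold and 88% of 100 changed 4-fold were recovered, with no other gene changed. In that simulation 7.52% of calls were false. These shares hold for few changed genes and do not carry over to the 5068 calls. The libraries labelled IL-6 KO also differed from both strains in table layout, so processing and group cannot be told apart.

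All 62 measured hair shaft genes were higher (62 adjusted over the list alone), with a median of 8.07, or 8.06 with the member at 0 reads held at its bound, and adjusted p = 8.29e-36 in camera (0.627 with an estimated correlation). Krtap19-9a, a keratin-associated protein of the hair cortex (chromosome 16), had 83.7 ± 60.3 CPM and 0 reads in C57BL/6, at least 494-fold higher. Krtap19-1 had 1 read in C57BL/6, a ratio of 2465 (counting interval 442 to 97431), and Krtap1-5 rose from 2.40 ± 3.41 to 1151 ± 752 CPM (8.85 on the log2 scale). The hair keratin Krt36 rose from 0.549 ± 0.222 to 60.8 ± 34.7 CPM (6.76 ± 0.647, adjusted p = 4.29e-04). Among inner root sheath genes and hair cycle regulators 29 of 37 were higher and 1 lower (29 and 1 adjusted over the list alone), with a median of 4.88 and adjusted p = 1.74e-11 (0.638 with an estimated correlation). Msx2, a transcription factor of the hair matrix, rose from 4.18 ± 1.78 to 130 ± 72.5 CPM (4.93 ± 0.513, adjusted p = 4.62e-04). Lef1, the Wnt effector of the hair matrix, chosen after its values were seen, rose by 5.15 ± 0.632 (adjusted p = 6.33e-04). By library, both hair lists together took 12.1%, 3.16% and 9.25% of reads in the libraries labelled IL-6 KO, so replicate 2 had the lowest share, and 0.0481% to 0.147% in C57BL/6.

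**Figure D2:**
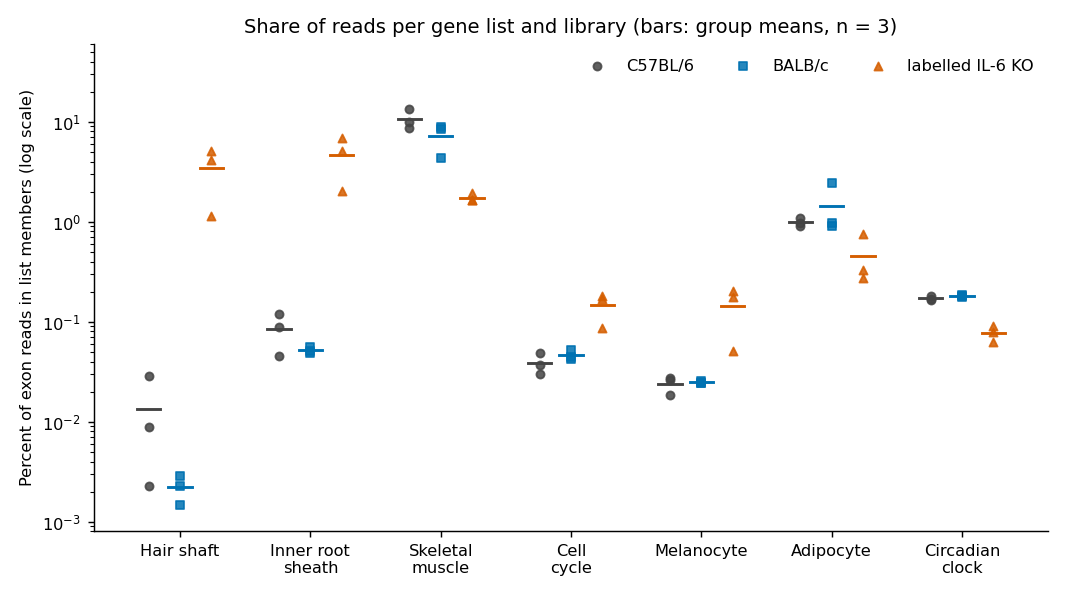
Percent of exon reads in members of 7 gene lists (vertical log axis), with 1 symbol per library, groups side by side and a bar at each group mean (n = 3). Hair shaft, inner root sheath, cell cycle and melanocyte shares are highest in the libraries labelled IL-6 KO, and the skeletal muscle share there is 1.74 ± 0.152% against 10.6 ± 2.40% in C57BL/6.

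Proliferation and pigment genes were higher in the same libraries. Of 34 cell cycle genes 30 were higher (33 adjusted over the list alone), with a median of 2.18 and adjusted p = 1.96e-13 (0.807 with an estimated correlation). Mki67, the Ki-67 antigen of dividing cells (chromosome 7, 135689784 to 135716361), rose from 26.4 ± 5.07 to 201 ± 87.9 CPM (2.92 ± 0.341, adjusted p = 5.42e-04), and Ccna2, cyclin A2, from 7.51 ± 0.922 to 53.9 ± 20.4 CPM. Of 19 melanocyte genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone, adjusted p = 5.03e-04, and 0.918 with an estimated correlation). Their median of 2.35 lay between 3.53 and 4.12 without IL-6 KO replicate 2 or any C57BL/6 or BALB/c library. Tyrp1, a melanosomal enzyme, rose from 3.47 ± 0.691 to 137 ± 106 CPM (5.30 ± 0.875, adjusted p = 0.00199).

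Keratins of activated epidermis were higher as well. In the epidermal stress list 13 of 16 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 3.12 and adjusted p = 5.92e-07 (0.627 with an estimated correlation). Krt6b rose from 2.37 ± 2.08 to 274 ± 172 CPM (6.78 ± 0.753, adjusted p = 4.99e-04), Krt16 from 14.5 ± 9.12 to 367 ± 232 and Krt17 from 390 ± 91.0 to 1496 ± 438. These keratins are made in stressed epidermis and also in the companion layer and outer root sheath of the hair follicle. Epidermal differentiation genes had 20 of 57 higher and 2 lower (23 and 2 adjusted over the list alone), a median of 0.59 and adjusted p = 0.0146 (0.938 with an estimated correlation). Without IL-6 KO replicate 2 it had adjusted p = 0.928 and a median of 0.14 (from 4.34e-05 to 0.928 over all alternatives). The list was not called with the Expression value column of the tables (adjusted p = 0.0623) or with library size alone as the scaling (0.0659) either. Sprr1b rose to 68.1 ± 20.4 CPM (6.93 ± 0.369, adjusted p = 1.12e-04), and Calml3, a calmodulin-like protein of epithelia, from 81.9 ± 1.91 to 272 ± 14.6 CPM (1.73 ± 0.143). Basal keratinocyte genes went both ways, with 2 of 20 higher and 6 lower (2 and 6 adjusted over the list alone, adjusted p = 0.792), and their median of 0.15 and mean of −0.17 differed in sign. Krt15, a keratin of basal and follicle stem cells, fell from 2470 ± 980 to 493 ± 204 CPM (−2.33 ± 0.371, adjusted p = 0.00174). The hyaluronan receptor Cd44 rose by 1.40 ± 0.131. Follicle stem cell genes also split, with 8 of 20 higher and 7 lower (9 and 7 adjusted over the list alone, adjusted p = 0.992).

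Most muscle and vessel genes, 9 of 18 nerve genes and 2 of 25 fat genes were lower. Of 30 muscle genes 29 were lower (29 adjusted over the list alone), with a median of −2.63 and adjusted p = 2.53e-17 (0.638 with an estimated correlation). Actn3 fell from 2680 ± 536 to 187 ± 25.2 CPM (−3.84 ± 0.276, adjusted p = 2.79e-04) and Mstn, the muscle growth inhibitor myostatin, from 176 ± 79.7 to 8.60 ± 4.46 (−4.38, adjusted p = 0.00156). The endothelial list had 16 of 25 lower (19 adjusted over the list alone), a median of −1.14 and adjusted p = 9.96e-06 (0.831 with an estimated correlation). Vwf fell by 1.51 on the log2 scale (adjusted p = 0.00198). Nerve and Schwann cell genes had 9 of 18 lower (9 adjusted over the list alone), a median of −0.99 and adjusted p = 5.9e-05 (0.562 with an estimated correlation). Mbp, myelin basic protein, fell from 207 ± 24.4 to 45.5 ± 16.3 CPM. Adipocyte genes had 2 of 25 lower (2 adjusted over the list alone), a median of −1.15 (−1.75 without IL-6 KO replicate 2) and adjusted p = 7.69e-04 (0.938 with an estimated correlation). Slc2a4, a glucose transporter of fat and muscle, fell from 178 ± 41.2 to 40.2 ± 6.05 CPM and Car3, a carbonic anhydrase of fat and muscle, from 4250 ± 1056 to 948 ± 530. Neither gene tells a change of fat apart from the muscle change given above. Mitochondrially encoded transcripts were 4.33 ± 0.250% of reads against 6.91 ± 1.79%, with 4 of 13 genes lower (9 adjusted over the list alone), a median of −0.74 and adjusted p = 0.021 (0.938 with an estimated correlation). This last call was lost without C57BL/6 replicate 3 (adjusted p = 0.105, median −0.49) or IL-6 KO replicate 2 or 3 (adjusted p = 0.0781 and 0.0605), and with unique exon reads or the Expression value column (adjusted p = 0.793 and 0.136, from 0.0036 to 0.793 over all alternatives).

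Most clock genes were lower. Of 19 clock genes 14 were lower and 2 higher (14 and 2 adjusted over the list alone), with a median of −1.15 and adjusted p = 1.45e-05 (0.562 with an estimated correlation). Dbp, a clock output transcription factor that peaks with the Per genes (chromosome 7, 45705088 to 45710203), fell from 212 ± 46.5 to 39.5 ± 7.09 CPM (−2.42 ± 0.201, adjusted p = 4.29e-04). Per3 (chromosome 4, 151003652 to 151044665) fell from 99.2 ± 6.63 to 29.7 ± 2.68 CPM (−1.74 ± 0.137, adjusted p = 4.2e-04), and Tef from 424 ± 32.3 to 121 ± 22.9. With the Expression value column, which is defined differently in these tables, Per3 stood at 0.14 (adjusted p = 0.513, from 1.59e-23 to 0.513 over all alternatives). The higher members were Nfil3, which represses Dbp targets (12.8 to 37.8 CPM, 1.55 on the log2 scale, adjusted p = 0.00352), and Arntl, the activator BMAL1, which peaks opposite to the Per genes (13.2 to 21.4 CPM, 0.69, adjusted p = 0.0496).

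**Figure D3:**
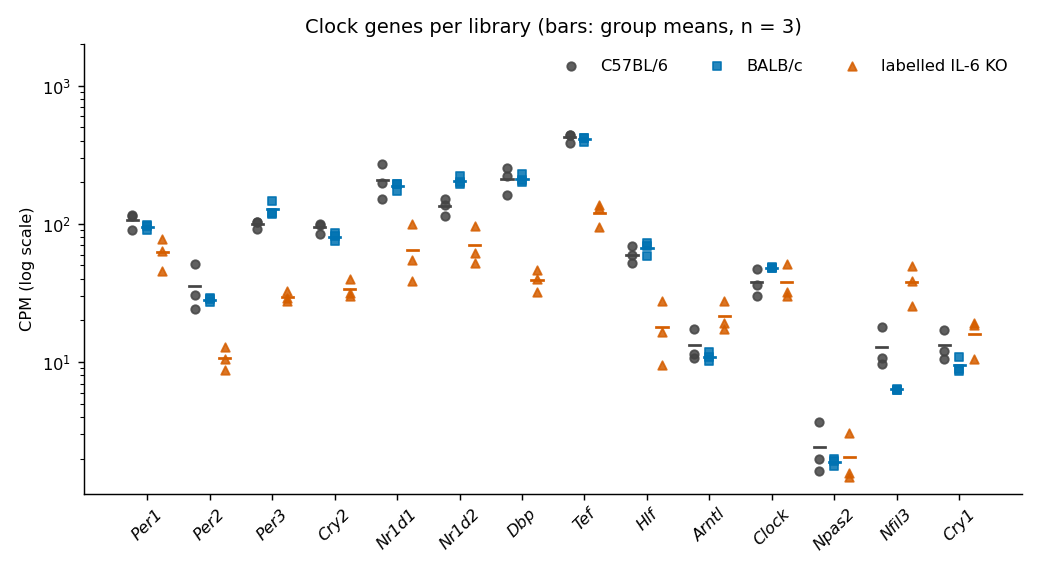
CPM of 14 clock genes (vertical log axis), with 1 symbol per library, groups side by side and a bar at each group mean (n = 3). Dbp stands at 39.5 ± 7.09 CPM in the libraries labelled IL-6 KO against 212 ± 46.5 in C57BL/6 and 213 ± 13.5 in BALB/c, while Nfil3 and Arntl are higher there.

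Components of the IL-6 pathway moved both ways. Of 27 measured members 8 were higher and 4 lower (9 and 4 adjusted over the list alone), with a median of −0.16 and a mean of 0.14, which differ in sign, and adjusted p = 0.917. Junb, an AP-1 factor induced by STAT3 (chromosome 8, 84974484 to 84978718), rose from 57.9 ± 13.3 to 172 ± 33.3 CPM (1.57 ± 0.193, adjusted p = 6.33e-04). The acute phase gene Saa3 rose from 0.386 ± 0.209 to 6.59 ± 2.20 (4.04 ± 0.548, adjusted p = 9.08e-04), and Pim1 by 0.84 ± 0.179 (adjusted p = 0.00646). Il6st, the shared signalling receptor gp130 (chromosome 13, 112464070 to 112510086), fell from 348 ± 26.0 to 195 ± 51.1 CPM (−0.83 ± 0.192, adjusted p = 0.0091). The type 1 list had 0 of 10 higher and 2 lower (0 and 2 adjusted over the list alone, adjusted p = 0.406), with Il12rb2 down from 11.6 ± 5.88 to 1.36 ± 0.937 CPM (−3.04 ± 0.613, adjusted p = 0.0051). The type 2 list had 1 of 17 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.406). Ccl24 fell from 9.88 ± 3.92 to 3.57 ± 0.978 CPM (−1.47 ± 0.412, adjusted p = 0.0217). This call was lost without C57BL/6 replicate 1 or 3 or IL-6 KO replicate 3 (adjusted p from 0.0651 to 0.087, and from 0.00452 to 0.087 over all alternatives). The Th17 and IL-23 list had 1 of 10 higher and 2 lower (1 and 2 adjusted over the list alone, adjusted p = 0.361), with a median of −0.40 and a mean of 0.08, which differ in sign. Il1b, interleukin-1 beta, stood at 0.351 ± 0.375 and 15.2 ± 15.6 CPM (5.29 ± 1.17, adjusted p = 0.00755).

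Antigen presentation genes had 0 of 32 higher and 10 lower (10 lower adjusted over the list alone), a median of −0.71 (−1.17 without IL-6 KO replicate 2) and adjusted p = 8.79e-05 (0.918 with an estimated correlation). IL-6 KO replicate 2 had 0.567% of reads in this list, above C57BL/6 (0.453% to 0.490%), with 0.219% and 0.268% in replicates 1 and 3. The class I gene H2-Q6 fell from 85.6 ± 15.6 to 23.6 ± 13.1 CPM (−1.85 ± 0.322, adjusted p = 0.00258). Immediate early genes had 12 of 34 higher and 1 lower (14 and 1 adjusted over the list alone), a median of 0.33 and adjusted p = 0.0185 (0.918 with an estimated correlation). It was not called without IL-6 KO replicate 2 (adjusted p = 0.169, from 0.00135 to 0.169 over all alternatives). Egr1, a growth factor response gene, rose from 36.1 ± 16.4 to 140 ± 32.4 CPM (1.95 ± 0.293, adjusted p = 0.00136). The remaining lists were not called. The antimicrobial list had 8 of 23 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.121), with S100a7a, a psoriasin-like alarmin, up from 1.56 to 103 ± 63.2 CPM (5.99 on the log2 scale). Xenobiotic response genes had 8 of 39 higher and 15 lower (10 and 16 adjusted over the list alone, adjusted p = 0.0522), with Gclc, of glutathione synthesis, up by 1.79 ± 0.242 and the glutathione transferase Gstm1 down by −1.27 ± 0.146. The sebaceous list had 8 of 34 higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.656), and its median of −0.00 and mean of 0.15 differed in sign.

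Other lists gave adjusted p-values in camera of 0.132 for T cells, 0.191 for matrix, 0.361 for neutrophils, 0.491 for mast cells, 0.596 for regulatory T cells, 0.613 for glucocorticoid response, 0.671 for blood, 0.679 for interferon-stimulated genes and 0.977 for macrophages. Of these, regulatory T cell and TGF-beta genes had 4 of 21 higher and 4 lower, and glucocorticoid response genes 3 of 16 higher and 7 lower, with the same counts adjusted over the list alone. The same holds for matrix genes (2 of 39 higher and 3 lower), macrophage genes (2 of 29 higher) and blood genes (1 of 8 higher). T cell genes had 1 of 17 lower (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2), mast cell genes 1 of 12 higher and 1 lower (1 and 0) and interferon-stimulated genes 1 of 42 higher (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2). The neutrophil list had 4 of 9 higher (4 higher and 2 lower adjusted over the list alone), and Fmod and Tnc of the matrix list moved apart (−2.22 ± 0.241 and 2.33 ± 0.270). Interferon-stimulated genes had a median of −0.04 and a mean of 0.10, which differ in sign. In the B cell list 1 of 4 measured members was higher and 2 lower (1 and 2 adjusted over the list alone). The higher member was Sdc1, a proteoglycan of plasma cells and of epithelia, at 299 ± 45.5 and 606 ± 81.6 CPM.

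**Figure D4:**
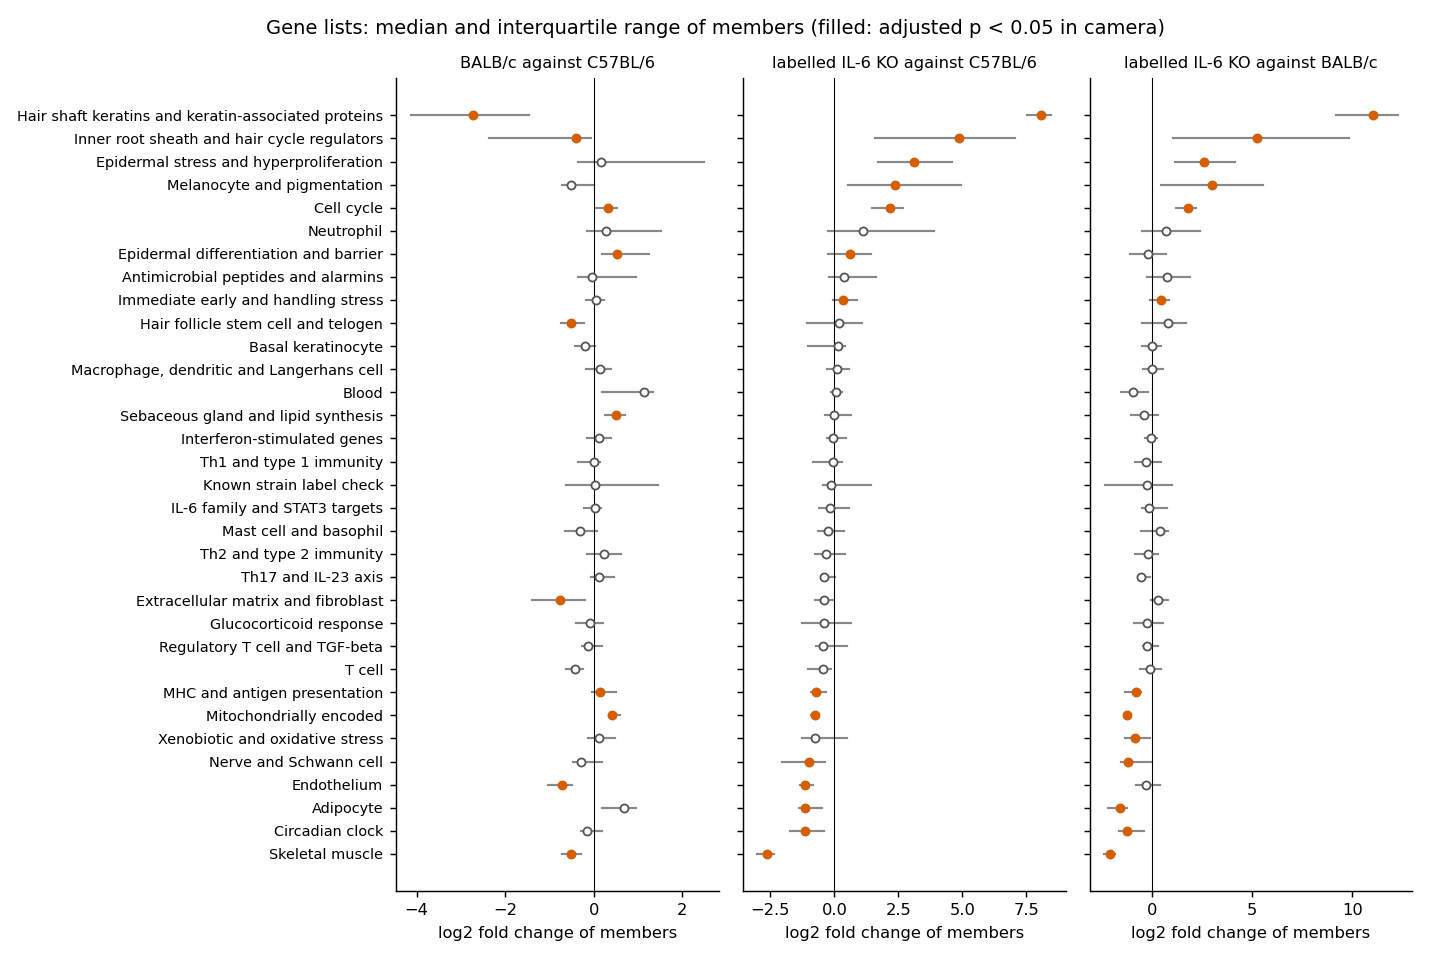
Median (point) and interquartile range (line) of the log2 fold changes of list members in the 3 comparisons, with members at 0 reads in a group held at their bounds, and filled points for lists called by camera at a preset correlation. The hair shaft list stands at 8.06 and 11.03 in the comparisons of the libraries labelled IL-6 KO with C57BL/6 and BALB/c, and the skeletal muscle list at −2.63 and −2.14.

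The libraries labelled IL-6 KO were also set against BALB/c. Hair keratins that were undetected in BALB/c skin were abundant there. Krt81, a keratin of the hair cortex (chromosome 15, 101459061 to 101463765), had 1611 ± 1026 CPM (SD, n = 3) against 0 reads, at least 9453-fold higher. Krtap15 had 1653 ± 1138 CPM, at least 9638-fold, and Krt33b at least 6097-fold. Most muscle genes and 12 of 25 fat genes were lower, with Myh4 down from 9302 ± 2849 to 638 ± 311 CPM (−3.87 ± 0.452, adjusted p = 4.94e-04) and Slc2a4, of fat and muscle, from 185 ± 20.4 to 40.2 ± 6.05 (−2.20 ± 0.198, adjusted p = 2.34e-04). Immune genes that marked BALB/c against C57BL/6 were also nearly absent, with Gbp2b at a ratio of 80.6 (27.3 to 393) and Ifi44l at 81.3 (14.3 to 3240), both higher in BALB/c.

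In this comparison 5370 genes were called (37.3%), 2867 higher and 2503 lower in the libraries labelled IL-6 KO, and 2880 differed at least 2-fold. The values of 5222 of them did not overlap, as they do by chance for 10% of genes not chosen by such a test. Without IL-6 KO replicate 3 the count was 3310. The table layout differs here too, so processing and group cannot be told apart.

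The hair shaft list had 62 of 62 higher (62 adjusted over the list alone), a median of 12.57 as fitted and 11.03 with its 34 members at 0 reads held at their bounds, and adjusted p = 2.41e-38 (0.627 with an estimated correlation). The inner root sheath list had 28 of 37 higher and 1 lower (28 and 1 adjusted over the list alone), a median of 5.25 and adjusted p = 1.85e-13 (0.627 with an estimated correlation). Cell cycle genes had 30 of 34 higher (32 adjusted over the list alone, median 1.76, adjusted p = 6.69e-11, and 0.893 with an estimated correlation), with Mki67 at 46.2 ± 6.19 CPM in BALB/c (2.12 ± 0.329). Epidermal stress genes had 12 of 16 higher and 1 lower (12 and 1 adjusted over the list alone, median 2.57, adjusted p = 4.2e-05, and 0.638 with an estimated correlation). Melanocyte genes had 13 of 19 higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 3.09e-04, and 0.918 with an estimated correlation), with a median of 3.00 that was 4.84 without IL-6 KO replicate 2 and 4.88 without BALB/c replicate 1. Differentiation genes split, with 12 of 57 higher and 8 lower (12 and 8 adjusted over the list alone, adjusted p = 0.849), and their median of −0.24 and mean of 0.36 differed in sign. Sprr1b was higher by 4.20 ± 0.288 (adjusted p = 5.58e-05).

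Lists with medians below 0 against BALB/c included muscle, with 28 of 30 lower (30 adjusted over the list alone, median −2.14, adjusted p = 1.07e-13, and 0.807 with an estimated correlation). Nerve genes had 11 of 18 lower and 1 higher (11 and 1 adjusted over the list alone, median −1.22, adjusted p = 9.15e-04, and 0.627 with an estimated correlation). Antigen presentation had 14 of 32 lower (17 adjusted over the list alone), a median of −0.82 (−1.35 without IL-6 KO replicate 2) and adjusted p = 5.31e-07 (0.918 with an estimated correlation). IL-6 KO replicate 2 also lay above BALB/c in share of reads (0.506% to 0.555%). H2-DMb2, a class II peptide loading chain, stood at 16.7 ± 3.39 and 2.41 ± 1.67 CPM (−2.74 ± 0.408, adjusted p = 0.00124). Adipocyte genes had 12 of 25 lower (20 adjusted over the list alone), a median of −1.62 (−0.80 without BALB/c replicate 1, whose adipocyte share was 2.47% of reads) and adjusted p = 1.15e-05 (0.918 with an estimated correlation). Clock genes had 14 of 19 lower and 2 higher (14 and 3 adjusted over the list alone, median −1.24, adjusted p = 3.97e-05, and 0.562 with an estimated correlation). Dbp fell by 2.42 on the log2 scale (SE 0.201, adjusted p = 1.58e-04), and Nfil3 and Arntl rose by 2.57 (adjusted p = 5.19e-04) and 0.97 (adjusted p = 0.0134). Mitochondrially encoded genes had 11 of 13 lower (12 adjusted over the list alone, median −1.28, adjusted p = 1.55e-04, and 0.918 with an estimated correlation), with mt-Nd2 at −1.67 ± 0.301 (adjusted p = 0.00293). That list call was lost with unique exon reads (adjusted p = 0.143) and with the Expression value column of the tables (0.435, the highest over all alternatives, whose lowest was 2.28e-05).

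Xenobiotic response genes had 9 of 39 higher and 20 lower (9 and 22 adjusted over the list alone), a median of −0.87 and adjusted p = 0.0111 (0.918 with an estimated correlation), with Gstm1 at −1.30 ± 0.146. Immediate early genes had 12 of 34 higher and 2 lower (12 and 2 adjusted over the list alone), a median of 0.42 and adjusted p = 0.0454 (0.918 with an estimated correlation). That call was lost without C57BL/6 replicate 1 (adjusted p = 0.0511), IL-6 KO replicate 2 (0.287, median 0.26), or BALB/c replicate 1 or 2 (0.106 and 0.0540), and with unique reads, the Expression value column or library size alone (0.0751, 0.135 and 0.0659, from 0.00429 to 0.287 over all alternatives). Of type 2 genes 0 of 17 were higher and 3 lower (0 and 3 adjusted over the list alone, adjusted p = 0.204). Ccl24 was lower by −3.01 ± 0.402 (28.5 ± 9.05 against 3.57 ± 0.978 CPM, adjusted p = 8.0e-04). Retnla was lower by −2.16 ± 0.542 (adjusted p = 0.013, but 0.0548 without IL-6 KO replicate 3, from 1.69e-04 to 0.0548 over all alternatives). Type 1 genes had 0 of 10 called by edgeR on either adjustment, with 3 at an unadjusted p under 0.05 and 2 by DESeq2 (median −0.31, adjusted p = 0.485 in camera). The Th17 and IL-23 list had 1 of 10 higher and 2 lower (1 and 3 adjusted over the list alone, adjusted p = 0.192). The IL-6 list had 9 of 27 higher and 3 lower (9 and 4 adjusted over the list alone, adjusted p = 0.737), with a median of −0.15 and a mean of 0.19, which differ in sign. Junb was higher by 1.40 ± 0.191.

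The other lists were not called against BALB/c. Camera gave adjusted p = 0.0798 for antimicrobial peptides (10 of 23 higher and 2 lower, 11 and 3 adjusted over the list alone), 0.204 for follicle stem cells (10 of 20 higher and 5 lower, on either adjustment), 0.213 for matrix (7 of 39 higher and 2 lower, 5 and 0 adjusted over the list alone) and 0.361 for the sebaceous list (5 of 34 higher and 8 lower, on either adjustment). Lgr5, a marker of cycling follicle stem cells, was higher by 2.17 ± 0.245 and Lgr6, of another follicle stem cell pool, lower by −1.65 ± 0.243. Adjusted p-values were 0.28 for interferon-stimulated genes, 0.356 for endothelium, 0.64 for T cells, 0.656 for neutrophils, 0.675 for regulatory T cells, 0.709 for glucocorticoid response, 0.799 for macrophages, 0.826 for basal keratinocytes and for blood, and 0.931 for mast cells. On either adjustment, 2 of 9 neutrophil genes were higher, 3 of 21 regulatory T cell genes higher and 4 lower, 3 of 16 glucocorticoid response genes higher and 4 lower, 4 of 20 basal keratinocyte genes higher and 2 lower, 1 of 8 blood genes higher, and 1 of 12 mast cell genes higher and 2 lower. Interferon-stimulated genes had 2 of 42 lower (1 adjusted over the list alone), endothelial genes 5 of 25 lower (0 adjusted over the list alone, 9 at an unadjusted p under 0.05, 8 by DESeq2) and macrophage genes 2 of 29 higher and 1 lower (2 and 0). EdgeR called 0 T cell genes on either adjustment, with 3 at an unadjusted p under 0.05 and 0 by DESeq2. The median and mean of the blood and mast cell lists differed in sign or from the direction of the test. Of the 4 measured B cell genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone).

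The joint test asked which genes differed among the 3 groups, and pairwise calls gave the genes that set 1 group apart from both others. Most of the latter belonged to the libraries labelled IL-6 KO, with 3608 genes apart, 2023 higher and 1585 lower. They were led by Krtap19-9a, Krtap19-1 and Krtap19-2 among the higher and by Mstn and Myh4 among the lower. BALB/c had 311 genes apart, 156 higher and 155 lower, with C1rb, H2-Q2 and Eno1b leading the higher and Skint3 and Skint9 the lower. H2-Q2, a nonclassical class I gene with the limit of H2-Q1, stood at 45.4 ± 4.73 CPM. C57BL/6 had 179, of which 96 were higher and 83 lower in C57BL/6. Tdh, a threonine dehydrogenase (chromosome 14, 63492347 to 63509092), had 2 reads in C57BL/6, 1.78 ± 0.612 CPM in BALB/c (ratio 16.6, interval 4.25 to 143) and 22.5 ± 1.21 CPM in the libraries labelled IL-6 KO (ratio 209, interval 57.3 to 1732). Aox4, an aldehyde oxidase that makes retinoic acid (chromosome 1, 58210397 to 58268597), stood at 0.936 ± 0.680 CPM in C57BL/6, 11.5 ± 2.98 in BALB/c (3.55 ± 0.429, adjusted p = 0.00244) and 26.7 ± 6.90 in the libraries labelled IL-6 KO (4.77 ± 0.424, adjusted p = 4.29e-04).

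Among 14415 genes, 5865 differed among the 3 groups. Unchanged simulated groups gave 0 genes apart in BALB/c or in the libraries labelled IL-6 KO in 20 simulations. With no gene changed, few calls could be made, so this outcome was largely fixed in advance. The count of any difference was 3582 without IL-6 KO replicate 3, and that of genes apart in the libraries labelled IL-6 KO was 2320 and 2179 without their replicate 1 or 3. Genes apart in BALB/c numbered 166, 201 and 175 without C57BL/6 replicate 1, 2 or 3, 544 and 198 without IL-6 KO replicate 2 or 3, and 181, 144 and 136 without BALB/c replicate 1, 2 or 3. Genes apart in C57BL/6 numbered 96, 104 and 55 without C57BL/6 replicate 1, 2 or 3, 383 and 81 without IL-6 KO replicate 2 or 3, and 85, 53 and 46 without BALB/c replicate 1, 2 or 3.

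Both comparisons against C57BL/6 were then set side by side. Fmod and Vwf were lower and Sprr1b, Lce1g, Elovl3 and Aox4 higher in both, and 179 genes were called in the same direction, 83 higher and 96 lower than in C57BL/6. Tnc, the matrix glycoprotein tenascin-C, was among 32 genes called in opposite directions (lower in BALB/c by −1.35 ± 0.289, higher in the libraries labelled IL-6 KO by 2.33 ± 0.270). Its BALB/c call was lost without any library except IL-6 KO replicates 1 and 2 (adjusted p from 0.0554 to 0.143, and with the Expression value column, library size alone or the replicate block 0.0553, 0.0647 and 0.0767, and from 0.00146 to 0.143 over all alternatives). Unchanged groups, with all 9 libraries simulated at the C57BL/6 mean, shared 0 calls in 20 simulations. As no gene was changed there, this 0 does not show how shared controls raise the overlap. Independent lists of these sizes would share 86.0 (45.1 higher and 40.9 lower). The C57BL/6 libraries are too few to split, and part of the excess may come from these shared controls. Over all genes the log2 fold changes had a correlation of −0.09 against 0.49 in the simulations and a covariance of −0.108 against 0.0555.

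A knockout allele can carry flanking DNA of the strain it was made in, so genes near Il6 were examined. Of 199 tested genes within 20 Mb of Il6 on chromosome 5, 65 (32.7%) were called between the libraries labelled IL-6 KO and C57BL/6, against 5003 of 14216 elsewhere (35.2%). The odds ratio was 0.893 (95% interval 0.652 to 1.21, p = 0.501 in a two-sided Fisher's exact test). With 35.2% of genes called elsewhere, a few genes changed by flanking DNA could go unseen, so this question stays open. The interval also treats neighbouring genes as independent. Between BALB/c and C57BL/6 the same window held 11 called genes (5.53%) against 3.38% elsewhere (odds ratio 1.67, interval 0.816 to 3.09, p = 0.111 in Fisher's exact test).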

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

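The test here, a comparison of all libraries of a group with all C57BL/6 libraries in a column that the comparisons do not use, was planned. Intron reads were a mean of 8.25% of gene reads in the libraries labelled IL-6 KO (8.13%, 7.80% and 8.84%) against 6.33% in C57BL/6 (6.18%, 7.09% and 5.73%), and each library labelled IL-6 KO lay above each C57BL/6 library. This was singled out because it is a signal in data outside the main measurement that lies above the control libraries. In BALB/c the values were 8.87%, 7.72% and 6.90%, which overlap with both groups. Reads across exon junctions were 42.8 ± 1.26% in the libraries labelled IL-6 KO, 42.2 ± 1.79% in BALB/c and 46.9 ± 0.161% in C57BL/6, so C57BL/6 stood apart in that measure. No technical or biological explanation was tested for these shares, and the group stays among the open ones, as does a separate round of processing.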

How the results depend on the processing

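The alternatives with unique exon reads, the Expression value column, library size only, and without hair, muscle and mitochondrial genes were chosen after seeing the data; the others were planned. The pseudocount, quantile, upper quartile and filter alternatives planned for normalized values were not run, because the tables hold counts. C57BL/6 replicate 1 is the only library whose file differs from those of its group, so setting it aside is the same as leaving out that replicate.

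With the replicate number as a block, 255 genes were called for BALB/c against C57BL/6, 178 were apart in BALB/c, and 93 were apart in C57BL/6, which is also the overlap of both comparisons with C57BL/6. The labels do not tie the numbers to pairs. Deviations within groups correlated at −0.212 to 0.0617 for the same number, so the block mostly costs degrees of freedom. Requiring a log2 fold change of at least 1 left 2709 and 2880 genes for the libraries labelled IL-6 KO against C57BL/6 and BALB/c, 3417 with any difference, 1974 apart in the libraries labelled IL-6 KO, and 94 apart in C57BL/6 and in the overlap, by construction. DESeq2 called 1023 genes for BALB/c against C57BL/6, with 525 apart in BALB/c and 382 apart in C57BL/6 and in the overlap, and it shared 490 of the 491 calls for BALB/c; the cause of the higher counts was not tested. Camera with an estimated correlation called 0 of the 99 list tests (6 had an unadjusted p under 0.05), and fry called 26, against 38.

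Leaving out 1 library gave 167 to 977 genes for BALB/c against C57BL/6 and 3238 to 6806 and 3310 to 7044 for the libraries labelled IL-6 KO against C57BL/6 and BALB/c. It gave 3582 to 7724 with any difference, 136 to 544 apart in BALB/c, 2179 to 5312 apart in the libraries labelled IL-6 KO, 46 to 383 apart in C57BL/6 and in the overlap, 35 to 44 list calls, and 60.5 to 70.6% of variance on the first component. The highest gene counts came without IL-6 KO replicate 2. Chi-square per degree of freedom was 48.5 and 33.2 between it and the others of its group and 6.71 between those, and all comparisons share 1 estimate of the spread. The odds ratio near Il6 was 0.955 and 0.941 with windows of 10 and 40 Mb.

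Of 8449 values of named genes under the alternatives, 7928 kept their direction and side of the threshold, 407 lost the threshold, 107 passed it, and 7 reversed. With unique exon reads, mt-Co3 reversed against BALB/c (0.57). With the Expression value column, Per3 went to 0.14 against C57BL/6 and 0.0373 against BALB/c in the libraries labelled IL-6 KO, mt-Nd3 and mt-Co3 to 5.60 and 9.44 against BALB/c, and Gvin1 and RP24-246F6.2 to 4.16 and 0.57 against C57BL/6. That column is defined differently in the tables labelled IL-6 KO, so these comparisons mix quantities. Of list directions, 0 of the called ones reversed in any alternative. At the depth and dispersion of these libraries, fold changes of 2 were recovered in 33% and 35% of simulated genes. Both shares hold for simulations with few changed genes, and how much of this limit comes from depth was not tested.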

Other observations

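The tests of the skeletal muscle share, of a separate batch, of the time of day, of copies called in opposite directions, and of genes apart in either strain under other splits were chosen only after the result was seen; the others were planned.

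Other splits of the libraries were used to ask whether chance could give as many calls. For each pairwise comparison, the 6 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many calls in edgeR: 491, 5068 and 5370 genes in the real splits and at most 0 in the others. Of 100 drawn splits of the 9 libraries, 1, the real one, gave as many genes with any difference (5865, highest other 3498). The real one alone also had a group with as many genes apart as the libraries labelled IL-6 KO (3608, highest other 3105). Such splits mostly measure whether these libraries stay together. The labels do not tie a library to 1 mouse, so the libraries may not be exchangeable, and chance is not excluded by these counts. For genes apart in BALB/c (311) or in C57BL/6 (179), the 6 libraries of the strains make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many in edgeR, against at most 0 in the others. Of the other splits of the 9 libraries, the 2 that kept the 3 libraries labelled IL-6 KO together gave 3380 and 3498 genes with any difference, and the remaining ones at most 119, which points to a structure of the samples in which these libraries stand together. As many list calls as the real 38 were found in 71 of the 100 splits (highest other 57), so the number of list calls cannot be set apart from chance. Called lists with 0 members called by edgeR rest on camera alone. The follicle stem cell list in BALB/c against C57BL/6, with 3 of 20 members lower, was also called by fry (adjusted p = 0.0113).

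For the large difference of the libraries labelled IL-6 KO, the first pattern, one hypothesis is that their hair follicles were in another stage of the hair cycle, and that follicle RNA may account for the other changes. With the percent of reads in the hair lists as a covariate, the 4976 genes called outside those lists kept a median 0.613 of their fold change (interquartile range 0.339 to 0.910, medians of 0.594 to 0.720 without each library), but the spread of the genes is wide, with quartiles of 0.174 and 1.27 without IL-6 KO replicate 2, so a linear effect of hair RNA as the main cause stays open. The hair share separates these libraries (3.16% or more) from all others (0.147% or less), and with it in the model 531 genes, against 5068, were called, and 0 in edgeR without IL-6 KO replicate 2, as the median SE of the 4976 genes rose from 0.230 to 0.340 (0.212 to 1.27 without that library) and their median absolute log2 fold change went from 1.05 to 0.618 (1.19 to 1.01). A loss of muscle that leaves all other tissues in proportion would raise the markers of all other cell types alike. Melanocyte genes (2.35, interquartile range 0.52 to 4.93) and adipocyte genes (−1.15, −1.40 to −0.48) lay 3.50 apart. They are the highest and lowest of the cell type lists, taken after their values were seen. The gap speaks only against such a loss of muscle alone, and does not show how much a muscle loss, with or without other tissues, contributes. A separate library or processing batch cannot be told apart from the group, because 0 libraries of other groups share the table layout of these, and the genotype stays open as untested.

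The second pattern was the clock genes of these libraries. A collection at another time of day may shift genes of opposite phase in opposite directions. The 5 opposite-phase genes had a median of 0.28 (0.00 to 0.69), against −1.57 (−1.74 to −1.01) for the other 14, and Npas2, of the first set, was not raised (−0.23, adjusted p = 0.708 in edgeR). Both sets were compared after their values were seen, and 2 of the 5 were called higher, so the time of day, for which the labels used here give no hour, stays open. With the hair share as a covariate, clock genes called lower kept a median 0.842 of their fold change, but 0.416 without IL-6 KO replicate 2, so a part played by the hair follicle stays open, and so does the genotype.

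The third pattern was near-identical copies that moved in opposite directions in BALB/c. Reads may go to another copy when a strain variant lies closer to it in the reference. Of the 491 called genes, 87 had a copy (17.7%, against 6.98% of uncalled genes, odds ratio 2.87, p = 7.75e-15 in Fisher's exact test), and adding the reads of the copies kept a median 0.422 of their fold change (0.219 to 0.661 over 2000 bootstrap draws). The 29 genes with a copy called in the other direction kept 0.193 (0.0875 to 0.298). Unrelated genes called in the other direction, put in place of the copies, kept 0.238 (0.158 to 0.351 over 1000 draws), so these sums do not decide, and a true difference between strains in these genes stays open. Single cases include Ahcy, at −4.86 alone and 0.03 with its copies, and Kpna2, at −2.66 and −0.01, both chosen after their values were seen.

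BALB/c replicate 2, the library with Xist reads, also had the highest level of Hbb-bs, a globin of red cells, at 1142 CPM against at most 235 in each other library, a gene chosen after its values were seen. Reads in the 10 most abundant genes took from 6.74% to 13.4% of exon reads over all libraries.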
